A study of Mus musculus with 98 samples.

How the data were processed

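RNA from the blood leukocytes (64 arrays) and the spleen (34 arrays) of mice was measured on 1-colour Affymetrix arrays with 22690 probe sets. Per the labels, the arrays belong to 3 models: burn injury, infusion of lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammation) and trauma-hemorrhage. Each array title carries a letter, A or E, and a code, c or x. For blood, the labels assign E to the injury or infusion and A to sham treatment. They do not explain the codes c and x, which are compared here as coded, and all spleen titles carry E. The LPS spleen titles also carry a version mark that other titles lack, and their numbers lie apart from those of all other arrays. Samples were grouped by tissue, model, code and letter into 18 groups of 4 to 6 arrays. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

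The deposited values were linear intensities, one per probe set and array, and how they were computed from the scanned images and scaled is not given in the sources used here. Each of the 6 array sets (a model in a tissue) had one lowest value, from 9.68 in burn spleen to 32.5 in LPS blood, at which the dimmest probe sets were held. This floor held 4.02% to 7.43% of the probe sets of an array. Median intensities were alike within a set (from 76.2 to 83.5 in burn spleen and from 138 to 145 in LPS blood) and differed between sets, so the sets appear to have been processed separately. Levels of different sets were therefore not compared, and only differences within a set were set side by side. The number of arrays limits the precision.

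The 64 control probe sets of the manufacturer were left out, which kept 22626. Symbols came from the platform's gene table, which gave 1 symbol to 20380 probe sets, several to 691 and none to 1555. Of the 21084 probe sets in that table, 20364 had an identifier that the reference gene table of assembly GRCm38 also holds, and that table served only to match older symbols. A gene was represented by its probe set with the highest mean, which left 14639 genes and unnamed probe sets. Intensities were taken as log2(value + 16). Because the quantiles of the arrays of a tissue differed by more than 0.2 log2, arrays were quantile normalized within each tissue, a rule made before the data were examined. Probe sets with a mean under the 30th percentile were left out, and 10247 were tested in each comparison.

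Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with 1 term per group and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. All tests are two-sided. In blood, E minus A was averaged over both codes, x minus c over both letters, and the interaction asked whether E minus A depends on the code. In spleen, x was compared with c. Differences between models and between tissues were tested as contrasts in fits of all groups concerned, and those between tissues used E arrays alone. For 23 gene lists (cell type markers and pathways), the members higher, lower and not past the threshold were counted over all genes and adjusted over the list alone, and limma's camera test compared each list with the other genes at a preset correlation of 0.01, adjusted over all lists and comparisons of a kind. The same test was run with an estimated correlation. Errors are standard errors (SE) of a log2 difference unless SD is given. An array's list score is the mean log2 value of the list's members. Where arrays of the lower group were at the floor, a difference is a lower bound.

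The comparisons, lists, filters, thresholds and most alternatives were chosen before the data were examined. So was the rule for named genes: in each comparison of letters or codes, the 8 genes with the largest positive and the 8 with the largest negative difference among those that passed, and the 3 members with the smallest p of each list that passed. A further set of genes, those higher or lower in all 6 comparisons of x and c, was chosen after the values were seen. The alternatives were other pseudocounts, scalings and filters, every probe set on its own, array weights, a robust variance, larger fits, single letters or codes, the runs of consecutive title numbers as a block, a 2-fold threshold and leaving out each array in turn. Alternatives chosen after seeing the data were scaling within each array set, each title-number run alone, leaving out a pair of burn arrays that stood apart, and the log2 ratio of 3' to 5' signal of the beta-actin control probe sets, a measure of RNA integrity, as a covariate. Array quality was compared between codes by permutation tests, adjusted over 24.

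The steps were tested on simulated data before use, with genes changed by known amounts. A change of 1 log2 was recovered in 98.6% to 100% of genes in the blood comparisons of letters and codes and in 85.7% to 90.4% in the interactions. A change of 0.5 was recovered in 87.7% to 96.9% and in 43.3% to 55.4%, respectively. The changed genes were drawn at random, so these shares do not hold for genes that vary more between arrays. For E minus A in LPS blood, for example, Acod1 differed by 1.15 ± 0.50 and did not pass (limma, adjusted p = 0.893). Between 2.56% and 6.67% of the simulated calls were false. In the simulated set test, the 1 list that had been changed was called and 0 others were. The simulated genes varied independently of each other, so false calls of lists with correlated members were not tested. Replicate arrays were checked for duplicates: over 221 pairs within groups, correlations of log2 values were 0.935 to 0.995, and at most 0.00941% of values above the floor were identical, so each array counted as 1 sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.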

Results

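Gene expression was measured in blood leukocytes and spleen of mice from 3 models of systemic inflammation: burn injury, infusion of LPS and trauma-hemorrhage. The 64 blood arrays fall into 4 groups per model. These are formed by letter (E, described as injured or infused, and A, described as sham) and by a code, c or x, that the labels leave unexplained. In burn blood there were 5 c and 4 x arrays of letter A, and 6 c and 5 x arrays of letter E. The numbers were 6, 5, 6 and 5 in LPS blood and 5, 5, 6 and 6 in trauma-hemorrhage blood, in the same order. The 34 spleen arrays all carry E, with 5 c and 6 x arrays for burn, 6 and 6 for LPS, and 6 and 5 for trauma-hemorrhage. Values below are differences in log2 intensity with their SE, and p-values are limma's unless another test is named.

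The first question, which the labels pose for blood, was how E arrays differed from A arrays, averaged over both codes. The lists of neutrophils and of inflammation had small positive medians in all 3 models, and few single genes passed. In trauma-hemorrhage blood (12 E and 10 A arrays) 3 of 10247 genes passed, each at adjusted p = 0.0307. N4bp2l1 was higher in E by 0.27 ± 0.05. Gsta2, a glutathione transferase, was lower at -0.54 ± 0.09 and Tpcn1, an endolysosomal cation channel, at -0.25 ± 0.04. In burn blood (11 E and 9 A arrays) limma called 0 genes, with 541 at an unadjusted p under 0.05. In LPS blood (11 E and 11 A arrays) it called 0, with 560 at that level, against 1091 in trauma-hemorrhage blood. Other fits called more: 257 in trauma-hemorrhage blood with all 12 blood groups in 1 fit, 59 among its c arrays alone, and 196 in LPS blood with array weights.

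Neutrophil genes lay higher in E as a list in each model. Their median was 0.38 in burn (15 measured, adjusted p = 3.7e-04), 0.35 in LPS (16 measured, adjusted p = 1.0e-04) and 0.25 in trauma-hemorrhage (16 measured, adjusted p = 0.00165). These calls ended at adjusted p = 0.713, adjusted p = 0.682 and adjusted p = 0.682 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Ngp, a neutrophil granule protein, differed by 0.92 ± 0.56 in burn and by 0.85 ± 0.28 in trauma-hemorrhage, and Cd177, a neutrophil surface protein, by 0.70 ± 0.28 in LPS. The score of the list lay on the E side in 6 of 11, 5 of 11 and 9 of 12 E arrays. Inflammatory cytokines and NF-kB targets had medians of 0.16, 0.27 and 0.22 (adjusted p = 2.6e-04, 2.4e-05 and 0.00195), each with adjusted p = 0.682 with an estimated correlation. Of their members 0 passed, also adjusted over the list alone. Acute phase and antimicrobial genes had medians of 0.27, 0.31 and 0.38 (adjusted p = 0.00299, 5.2e-05 and 7.4e-05), each with adjusted p = 0.682 with an estimated correlation. Of these, 0 passed over all genes, and 2 passed in trauma-hemorrhage blood adjusted over the list alone. In burn blood B cell genes had a median of -0.16, and 0 of 14 members passed, also adjusted over the list alone. The list test gave adjusted p = 2.6e-04, and adjusted p = 0.682 with an estimated correlation.

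Interferon response genes lay higher in E as a list in LPS blood. The list median was 0.18, 0 of its 21 measured members passed over all genes and 5 passed adjusted over the list alone. Its score lay on the E side in 10 of 11 E arrays. The set test gave adjusted p = 1.6e-12, and adjusted p = 0.0770 with an estimated correlation. Cmpk2 (0.51 ± 0.11), Ifit1 (0.76 ± 0.17) and Gbp2 (0.77 ± 0.19), all induced by interferon, had the smallest p of the list, with adjusted p = 0.432, 0.432 and 0.596 over all genes. Platelet genes had a median of -0.10 in LPS blood, where the list passed (adjusted p = 3.7e-04) although 0 of its 11 members did, also adjusted over the list alone. In trauma-hemorrhage blood their median was -0.27, with 0 of 11 passed and 8 adjusted over the list alone (adjusted p = 3.7e-07). Both platelet calls had adjusted p = 0.682 with an estimated correlation. Immediate early genes had a median of 0.11 in trauma-hemorrhage blood (0 of 22 passed, also adjusted over the list alone), and their score lay on the E side in 11 of 12 E arrays. Their test gave adjusted p = 3.7e-04, and adjusted p = 0.682 with an estimated correlation. Heat shock and unfolded protein genes had a median of 0.07 in LPS blood (0 of 16 passed, also adjusted over the list alone). Their test gave adjusted p = 0.0253, and adjusted p = 0.682 with an estimated correlation.

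Several of these signals turned with the code. Among x arrays alone the burn medians were -0.08 for neutrophil genes, 0.17 for B cell genes, -0.06 for the inflammatory list and -0.13 for acute phase genes. There the B cell list passed in the direction opposite to its call over both codes (camera at the preset correlation, adjusted p = 0.00211). Among c arrays alone the LPS medians were -0.23 for neutrophil genes, -0.08 for the inflammatory list and -0.09 for acute phase genes. In burn blood the c arrays of letter E included replicates 4 and 5, with neutrophil scores of 11.1 and 10.8, against 8.13 to 8.87 in the other 4. Without this pair the burn neutrophil median was -0.02. The trauma-hemorrhage count moved between 0, for example without c of letter A replicate 3, and 81, without c of letter E replicate 6, and by over 1.5 times in 17 of 22 such fits. In LPS blood it was 7 without x of letter E replicate 5. Title numbers fall into 2 consecutive runs within each blood set. With the run as a block limma called 0, 0 and 3 genes, and within either run alone 0 in each model.

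**Figure D1:**
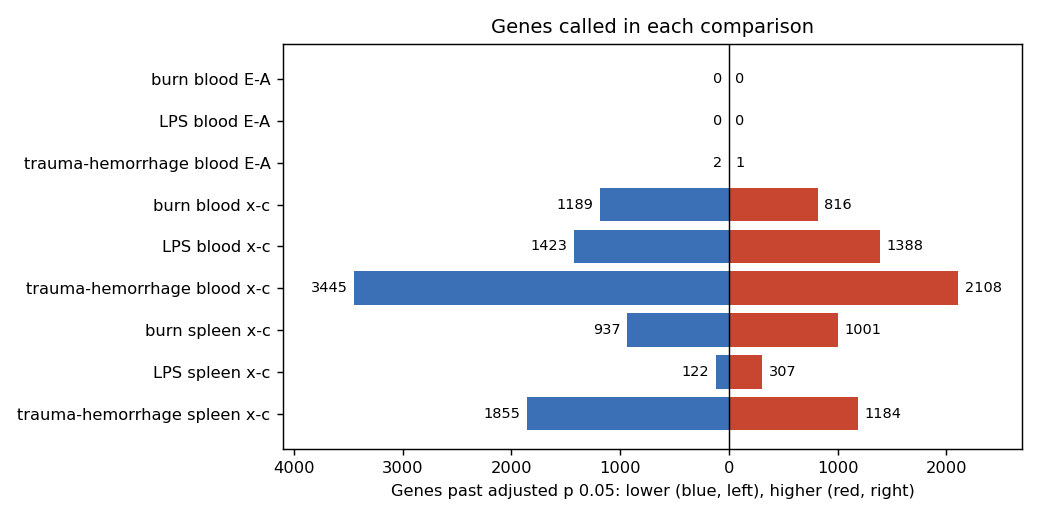
Number of genes that passed an adjusted p of 0.05 (x axis) in each comparison, split into those higher and those lower. Comparisons of x and c called between 429 and 5553 genes, and comparisons of E and A at most 3.

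In burn blood (9 x and 11 c arrays, averaged over letters) the largest rises in x included several genes of inflammation, although fewer than 50% of the inflammatory list passed, as given below. Cxcl2, a chemokine that draws neutrophils, rose by 3.49 ± 0.64 (11.2-fold), Jdp2 by 2.97 ± 0.37, Ets2 by 2.72 ± 0.35 and Acod1, which makes itaconate, by 2.40 ± 0.50. Il1r2, the decoy receptor of interleukin 1, was 8.02-fold higher (log2 SE 0.48). Basp1 (2.65 ± 0.33), Tgm2 (2.40 ± 0.23) and Arg2 (2.37 ± 0.40) completed the 8 largest rises. The largest falls included genes of lymphocytes. Ltb, a lymphotoxin chain, changed by -1.61 ± 0.14, Cd55 by -1.44 ± 0.16, and the B cell receptor chains Cd79b and Cd79a by -1.43 ± 0.17 and -1.42 ± 0.16. Cr2, a complement receptor of B cells, changed by -1.38 ± 0.12. Each of these 13 genes lay on the named side in 9 of 9 x arrays, compared with the c mean of the same letter. Of the 6 probe sets of Tgm2 the smallest difference was 0.02, so not all of them rose by as much. The same holds for genes named below with another probe set, Zbtb16 (0.09), Tfrc (-0.04), Cdkn1a (0.17) and Prf1 (-0.10).

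B cell genes fell in 13 of 14 measured members and rose in 0 (14 adjusted over the list alone). Their median was -0.92, with adjusted p = 3.2e-13, and adjusted p = 0.462 with an estimated correlation. NK cell genes fell in 5 of 10 (6 adjusted over the list alone), among them Prf1, which encodes perforin, at -0.45 ± 0.07. The NK cell median was -0.23, with adjusted p = 0.00236, and adjusted p = 0.462 with an estimated correlation. T cell genes fell in 5 of 17, also adjusted over the list alone. The T cell median was -0.13, with adjusted p = 0.0449, and adjusted p = 0.713 with an estimated correlation. Neutrophil genes rose in 8 of 15 (10 adjusted over the list alone), among them the calprotectin subunits S100a9 at 1.55 ± 0.30 and S100a8 at 1.42 ± 0.28. The neutrophil median was 1.26, with adjusted p = 8.7e-06, and adjusted p = 0.486 with an estimated correlation.

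Genes induced by glucocorticoids rose in 11 of 15 (13 adjusted over the list alone), with the clock gene Per1 at 1.07 ± 0.09 and Zbtb16 at 1.08 ± 0.19. The glucocorticoid median was 0.69, with adjusted p = 4.6e-09, and adjusted p = 0.462 with an estimated correlation. The inflammatory list had 12 members higher and 1 lower of 29, also adjusted over the list alone, with a median of 0.07 and a mean of 0.57. Its test gave adjusted p = 0.00343, and adjusted p = 0.554 with an estimated correlation. Acute phase genes rose in 4 of 12, also adjusted over the list alone, with a median of 0.62. Their test gave adjusted p = 0.00282, and adjusted p = 0.523 with an estimated correlation. Immediate early genes had 7 higher and 3 lower of 22 (8 and 3 adjusted over the list alone), with Rgs1 at 1.57 ± 0.07. Here the test gave adjusted p = 0.0202, and adjusted p = 0.463 with an estimated correlation. Apoptosis and DNA damage genes had 5 higher and 1 lower of 13 (6 and 2 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 1.39 ± 0.12. For this list the test gave adjusted p = 0.0199, and adjusted p = 0.462 with an estimated correlation.

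In the heat shock list 5 members rose and 1 fell of 17, also adjusted over the list alone, led by the chaperone Hspa1b at 2.23 ± 0.18. Its set test gave adjusted p = 0.0307, and adjusted p = 0.486 with an estimated correlation. Erythroid genes had 2 higher and 1 lower of 13, also adjusted over the list alone, with Tfrc, the transferrin receptor, at 0.51 ± 0.10. The erythroid median was 0.07, with adjusted p = 0.0401, and adjusted p = 0.554 with an estimated correlation. Interferon response genes had 4 members higher and 1 lower of 20, also adjusted over the list alone, and did not pass as a list (median 0.03, adjusted p = 0.498).

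In all, 2005 genes passed in burn blood, 816 higher and 1189 lower. The pair of c arrays with high neutrophil scores, above, also had low B cell scores (8.83 and 9.08, against 9.65 to 9.95 in the rest of their group), and without it 2942 genes passed. With the title-number run as a block 1978 passed, and within the first run 1240. Fewer passed within the second run, which held fewer arrays. Its only x array of letter A was replicate 4, so its count is not given and does not show whether the calls repeat. Among arrays of letter A 1577 genes passed, and of letter E 661. The pair of c arrays that stood apart belongs to letter E, which was not fitted alone without it. In letter E alone Cxcl2 (2.65, adjusted p = 0.0774), Il1r2 (2.14, 0.0538), Acod1 (1.35, 0.288), Arg2 (1.76, 0.0553), S100a9 (1.09, 0.130) and S100a8 (1.04, 0.116) did not pass. The list calls for T cell (adjusted p = 0.449), erythroid (0.326), immediate early (0.0519), inflammatory (0.336), apoptosis (0.0805) and acute phase genes (0.364) also ended in letter E. In letter A alone Tfrc (0.41, adjusted p = 0.0667) and the heat shock list (median 0.07, adjusted p = 0.172) did not pass.

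In LPS blood (10 x and 12 c arrays) the largest rise in x was Acod1 at 2.30 ± 0.50, followed by proteins of neutrophil granules and of the first defence against bacteria. Ngp rose by 2.23 ± 0.50, Lcn2, which binds bacterial siderophores, by 2.21 ± 0.53 and Mmp8, a collagenase, by 2.09 ± 0.42. Cd177 rose by 2.08 ± 0.28 and Pglyrp1, which binds peptidoglycan, by 2.06 ± 0.27. Clec4e, a receptor for mycobacterial glycolipid, rose by 2.03 ± 0.44 and Cxcl2 by 1.92 ± 0.53. These 8 genes were higher in 8 to 10 of 10 x arrays. The falls were smaller, with Adgre4 at -0.99 ± 0.22, Zfp825 at -0.99 ± 0.07, Map3k12 at -0.97 ± 0.07 and Birc6 at -0.94 ± 0.12. Adgre4, Map3k12 and Birc6 each have another probe set, with differences of -0.05, 0.04 and 0.04. These falls were therefore not seen in all probe sets of the genes.

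Neutrophil genes rose in 13 of 16 measured members and fell in 0, also adjusted over the list alone. Their median was 0.94, with adjusted p = 1.3e-06, and adjusted p = 0.462 with an estimated correlation. Acute phase genes rose in 8 of 12, also adjusted over the list alone, with Cebpb, a transcription factor of acute inflammation, at 1.29 ± 0.17 and Slpi, a protease inhibitor, at 1.20 ± 0.18. The acute phase median was 1.19, with adjusted p = 3.0e-05, and adjusted p = 0.462 with an estimated correlation. The inflammatory list had 17 members higher and 1 lower of 26, also adjusted over the list alone. Among them were the NF-kB pathway genes Bcl3 at 1.36 ± 0.20, Nfkbie at 1.03 ± 0.13 and Relb at 0.92 ± 0.12. The inflammatory median was 0.49, with adjusted p = 1.8e-06, and adjusted p = 0.462 with an estimated correlation. Platelet genes rose in 7 of 11, also adjusted over the list alone, with Gp9 at 0.54 ± 0.11. The platelet median was 0.22, with adjusted p = 9.3e-04, and adjusted p = 0.486 with an estimated correlation.

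Interferon response genes shifted little, with 7 higher and 1 lower of 21 (8 and 1 adjusted over the list alone). The interferon median was 0.20, with adjusted p = 0.0252, and adjusted p = 0.523 with an estimated correlation. Irf1 rose by 0.46 ± 0.07 and Usp18 by 0.46 ± 0.10, and the probe sets of Rsad2 were called in both directions, from -0.25 to 0.46. In the apoptosis list 4 of 13 rose (6 adjusted over the list alone), with a median of 0.10. Its test gave adjusted p = 0.0161, and adjusted p = 0.462 with an estimated correlation. B cell genes did not pass as a list (1 higher and 3 lower of 14, 1 and 4 adjusted over the list alone, median -0.14, adjusted p = 0.309).

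In all, 2811 genes passed in LPS blood, 1388 higher and 1423 lower. The beta-actin log2 ratio of 3' to 5' signal was 1.07 ± 0.105 (SD) in x and 1.58 ± 0.0587 (SD) in c arrays (permutation test, adjusted p = 2.4e-04). With it as a covariate 412 of the 2811 genes passed, and 0 called members of the neutrophil, inflammatory and interferon lists did. Among genes named above, Lcn2 (-0.06) and Usp18 (-0.25) then changed sign. The list calls ended for neutrophil genes (median 0.10, adjusted p = 0.930), interferon (-0.08, 0.195), acute phase (-0.03, 0.6246), inflammatory (0.14, 0.930), platelet (0.18, 0.251) and apoptosis genes (0.12, 0.536). In this set the ratio was at most 1.27 in x and at least 1.49 in c arrays, so it separates the codes. The median SE of the called genes rose from 0.069 to 0.218, so these losses do not tell RNA quality and the code apart. As a block, the title-number run gave 2879 genes, the first run alone 2785 and the second 470. Letters A and E alone gave 1258 and 1650.

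**Figure D2:**
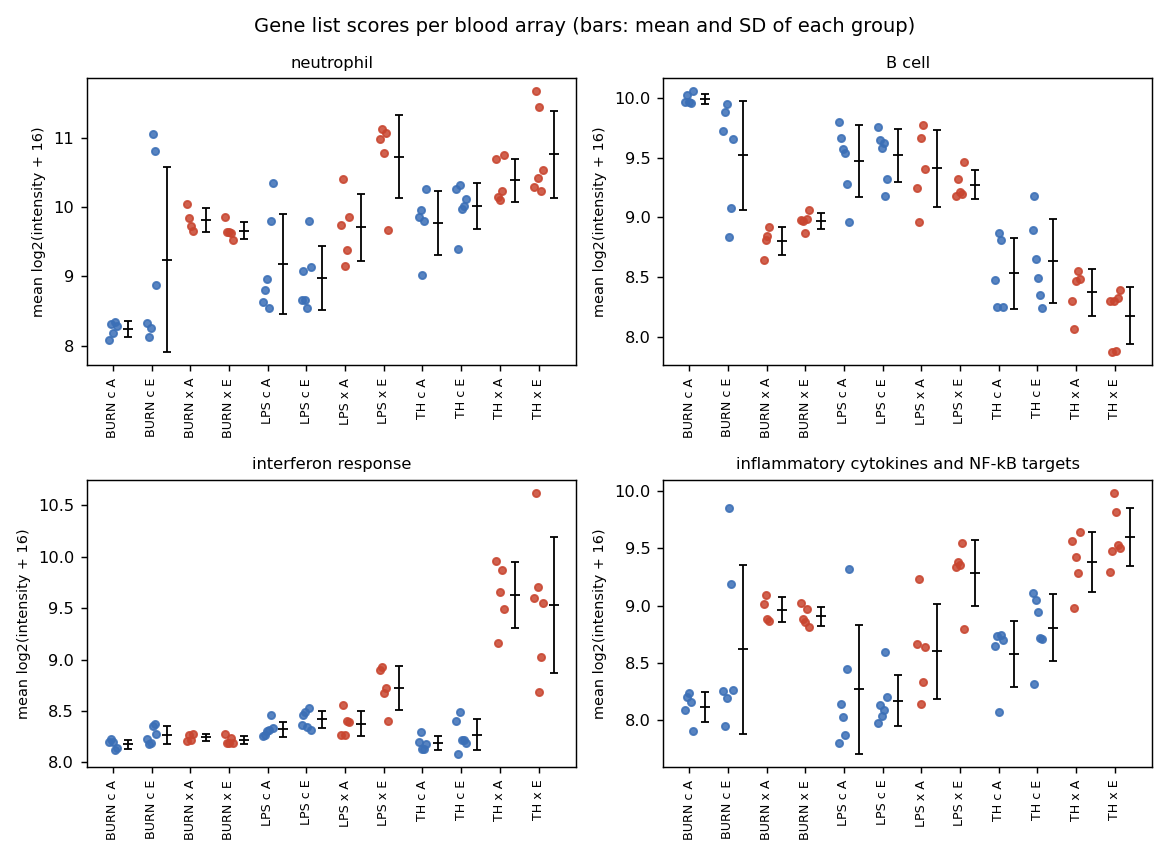
List score of each blood array (y axis, mean log2 value of the list's members) by group, with the mean and SD of each group. The lists are neutrophil, B cell, interferon response and inflammatory genes. The median x minus c difference of interferon response genes was 1.48 in trauma-hemorrhage, against 0.03 in burn and 0.20 in LPS blood. That of B cell genes was -0.92 in burn blood.

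In trauma-hemorrhage blood (11 x and 11 c arrays) the genes higher in x were led by Saa3, an acute phase protein, at 3.96 ± 0.20 (15.6-fold), and by genes induced by interferon. Among the latter the GTPase Gbp2 rose by 3.37 ± 0.27, Parp14 by 2.75 ± 0.20 and the chemokine Cxcl10 by 2.70 ± 0.35. Gbp6, another such GTPase, rose by at least 2.72 ± 0.19, with 9 of the 11 c arrays at the floor. Ms4a6d (3.19 ± 0.24), Acod1 (2.94 ± 0.31) and Ngp (2.71 ± 0.28) also rose, and each of these 8 genes was higher in 11 of 11 x arrays. The largest falls were Fbxo9 (-1.57 ± 0.13), Slc40a1, the iron exporter ferroportin (-1.45 ± 0.28), and Bsdc1 (-1.39 ± 0.12). Trim10, which red cell precursors express, changed by -1.26 ± 0.14, and Lmo2, a transcription factor of blood formation, by -1.19 ± 0.09. Other probe sets of Fbxo9, Slc40a1 and Bsdc1 fell by less, at -0.58, -0.65 and -0.82.

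Interferon response genes rose in 20 of 23 measured members and fell in 0, also adjusted over the list alone, with Ifi47 at 2.20 ± 0.19 and Irgm1 at 1.74 ± 0.14. The interferon median was 1.48, with adjusted p = 2.8e-12, and adjusted p = 0.462 with an estimated correlation. The inflammatory list had 17 higher and 2 lower of 29, also adjusted over the list alone. The inflammatory median was 0.58, with adjusted p = 8.7e-06, and adjusted p = 0.462 with an estimated correlation. Acute phase genes rose in 7 of 13 and fell in 0, also adjusted over the list alone. The acute phase median was 0.98, with adjusted p = 0.00323, and adjusted p = 0.486 with an estimated correlation. Monocyte genes rose in 6 of 10 (8 adjusted over the list alone), among them the LPS receptor Cd14 at 2.20 ± 0.21 and the Fc receptor Fcgr1 at 1.22 ± 0.18. The monocyte median was 0.48, with adjusted p = 0.00282, and adjusted p = 0.463 with an estimated correlation. Neutrophil genes had 10 higher and 3 lower of 16, also adjusted over the list alone. The neutrophil median was 0.42, with adjusted p = 0.0124, and adjusted p = 0.583 with an estimated correlation.

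Erythroid genes fell in 9 of 13, also adjusted over the list alone, with Car2, a carbonic anhydrase, at -0.93 ± 0.15. The erythroid median was -0.20, with adjusted p = 0.0122, and adjusted p = 0.486 with an estimated correlation. The heat shock and unfolded protein list had 10 higher and 2 lower of 16, also adjusted over the list alone, led by Hspa5, a chaperone of the endoplasmic reticulum, at 1.24 ± 0.13. Its median was 0.56, with adjusted p = 0.0161, and adjusted p = 0.523 with an estimated correlation. Apoptosis genes had 6 higher and 3 lower of 15, also adjusted over the list alone. Casp4, an inflammatory caspase, rose by 1.84 ± 0.17 and the death receptor Fas by 1.39 ± 0.16. The apoptosis median was 0.17, with adjusted p = 0.0413, and adjusted p = 0.462 with an estimated correlation.

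In all, 5553 genes passed in trauma-hemorrhage blood, 2108 higher and 3445 lower. The split rested on the scaling: with values as deposited 2733 were higher and 2473 lower, and with array medians subtracted 2814 and 2448. The beta-actin ratio was 1.42 ± 0.191 (SD) in x and 1.99 ± 0.135 (SD) in c arrays (permutation test, adjusted p = 2.4e-04). The share of probe sets at the floor was higher in x by 0.355 percentage points (permutation test, adjusted p = 0.0124). With the actin ratio as a covariate 16 genes passed, and the median size of the 5553 differences went from 0.30 to 0.14. The neutrophil median was then -0.10 and the erythroid median -0.01 with the opposite sign of its test, so both list calls ended. The monocyte (median 0.10, adjusted p = 0.3004) and acute phase calls (0.11, 0.398) ended too. At the preset correlation the interferon, inflammatory, heat shock and apoptosis list calls did not end. Of their single genes, however, 0 of 20 called interferon genes and 1 of 19 called inflammatory genes passed. Called inflammatory genes had 82.6% of their size and called interferon genes 33.6%. Here too the ratio separates the codes, at most 1.65 in x and at least 1.79 in c arrays. The median SE of the called genes rose from 0.072 to 0.158, so lost calls do not tell RNA quality and the code apart. As a block, the run gave 5559 genes, the first run alone 1257 and the second 4760, and letters A and E alone gave 4069 and 3150.

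**Figure D3:**
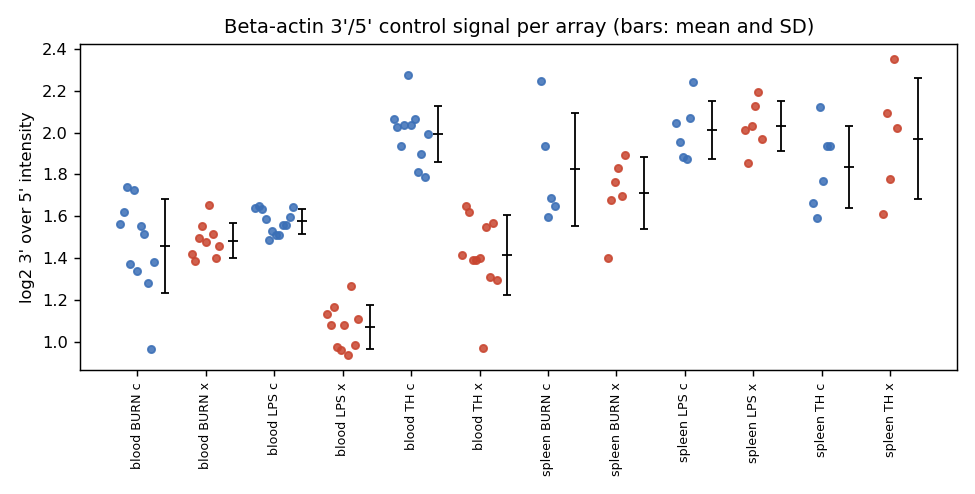
Log2 ratio of 3' to 5' signal of the beta-actin control probe sets (y axis) in each array, by array set and code. In LPS and trauma-hemorrhage blood x arrays lay lower than c arrays, by -0.506 and -0.580 on average, and in the other sets the difference did not pass.

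Whether E minus A depended on the code was tested as an interaction. By limma 0 genes passed in burn, LPS and trauma-hemorrhage blood, with 1245, 776 and 798 at an unadjusted p under 0.05. Neutrophil genes had medians of opposite sign in burn and LPS blood, a contrast that was not tested. Their median interaction was -1.06 in burn (0 of 15 passed, also adjusted over the list alone, adjusted p = 4.7e-05, and adjusted p = 0.490 with an estimated correlation). In LPS blood it was 1.11 (0 of 16 passed and 5 adjusted over the list alone, adjusted p = 2.0e-09, and adjusted p = 0.424 with an estimated correlation). The inflammatory list followed, at -0.37 in burn (0 of 29 passed, also adjusted over the list alone, adjusted p = 3.6e-04, and adjusted p = 0.490 with an estimated correlation). In LPS blood it was at 0.73 (0 of 26 passed and 7 adjusted over the list alone, adjusted p = 1.2e-09, and adjusted p = 0.424 with an estimated correlation). Without x of letter E replicate 5 the LPS count was 71, and without x of letter A replicate 4 the burn count was 2. Without the pair of burn c arrays the burn medians were -0.32 for neutrophil genes and -0.09 for the inflammatory list, so most of their size came from that pair. The burn count without the pair was 9, whereas the run as a block left 0 in each model.

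In burn spleen (6 x and 5 c arrays) the largest rises in x included a chemokine, chaperones and genes induced by glucocorticoids. Cxcl2 rose by 3.68 ± 0.28 (12.8-fold), the chaperones Hspa1b and Hspa1a by 3.31 ± 0.53 and 2.33 ± 0.55, and Hdc, which makes histamine, by 3.10 ± 0.22. Il1r2 rose by 2.69 ± 0.13, Dusp1, a phosphatase of MAP kinases, by 2.15 ± 0.18 and Per1 by 2.07 ± 0.13. Another probe set of Hdc differed by 0.30. One of the 5 c arrays was at the floor for Hdc, and for Cutal, higher by at least 2.50 ± 0.11, all 5 were. The largest falls included genes of red blood cell formation. Alas2, the first enzyme of heme synthesis in these cells, changed by -2.99 ± 0.15 and the globin Hbb-b2 by -2.95 ± 0.19, with 2 of 6 x arrays at the floor for the latter. Kcnq5, a potassium channel (-2.16 ± 0.11, 1 of 6 x arrays at the floor), Cdkn2d (-1.98 ± 0.13), Gdpd2 (-1.84 ± 0.16) and Car2 (-1.58 ± 0.17) followed. Each of these genes lay on the named side in 6 of 6 x arrays. Another probe set of Hbb-b2 differed by -1.41.

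Genes induced by glucocorticoids rose in 11 of 14 members and fell in 0, also adjusted over the list alone. The glucocorticoid median was 1.24, with adjusted p = 1.6e-13, and adjusted p = 0.00595 with an estimated correlation. B cell genes fell in 10 of 15 (11 adjusted over the list alone), with Cr2 at -0.79 ± 0.06. The B cell median was -0.33, with adjusted p = 8.3e-08, and adjusted p = 0.0181 with an estimated correlation. T cell genes rose in 8 of 17 (9 adjusted over the list alone), among them Il7r, the interleukin 7 receptor, at 1.29 ± 0.14 and the costimulatory receptor Cd28 at 1.30 ± 0.20. The T cell median was 0.41, with adjusted p = 7.9e-07, and adjusted p = 0.282 with an estimated correlation. Markers of red pulp macrophages, which recycle the iron of red cells, fell in 11 of 11, also adjusted over the list alone. Slc40a1 and Cd5l changed by -1.16 ± 0.12 and -1.16 ± 0.14. The macrophage median was -0.75, with adjusted p = 3.4e-10, and adjusted p = 0.157 with an estimated correlation.

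Erythroid genes fell in 5 of 10 (7 adjusted over the list alone). The erythroid median was -0.45, with adjusted p = 9.0e-06, and adjusted p = 0.0551 with an estimated correlation. NK cell genes fell in 6 of 11 (7 adjusted over the list alone). The NK cell median was -0.39, with adjusted p = 0.00285, and adjusted p = 0.405 with an estimated correlation. Monocyte genes fell in 5 of 9 and rose in 1, Cd14 at 2.03 ± 0.15, also adjusted over the list alone. The monocyte median was -0.47, with adjusted p = 0.0471, and adjusted p = 0.513 with an estimated correlation. The inflammatory list had 10 higher and 4 lower of 25 (11 and 5 adjusted over the list alone), with a median of 0.09 and a mean of 0.48. Its test gave adjusted p = 0.00288, and adjusted p = 0.0891 with an estimated correlation. The heat shock list did not pass (5 higher and 0 lower of 17, also adjusted over the list alone, median 0.16, adjusted p = 0.0520). Immediate early genes had 7 higher and 2 lower of 18 (8 and 2 adjusted over the list alone). Here the test gave adjusted p = 0.0108, and adjusted p = 0.174 with an estimated correlation. In all, 1938 genes passed, 1001 higher and 937 lower, or 1229 higher and 701 lower with array medians subtracted. The title numbers of burn spleen run in 1 block per code, so a run and the code cannot be separated there, and the same holds in trauma-hemorrhage spleen.

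**Figure D4:**
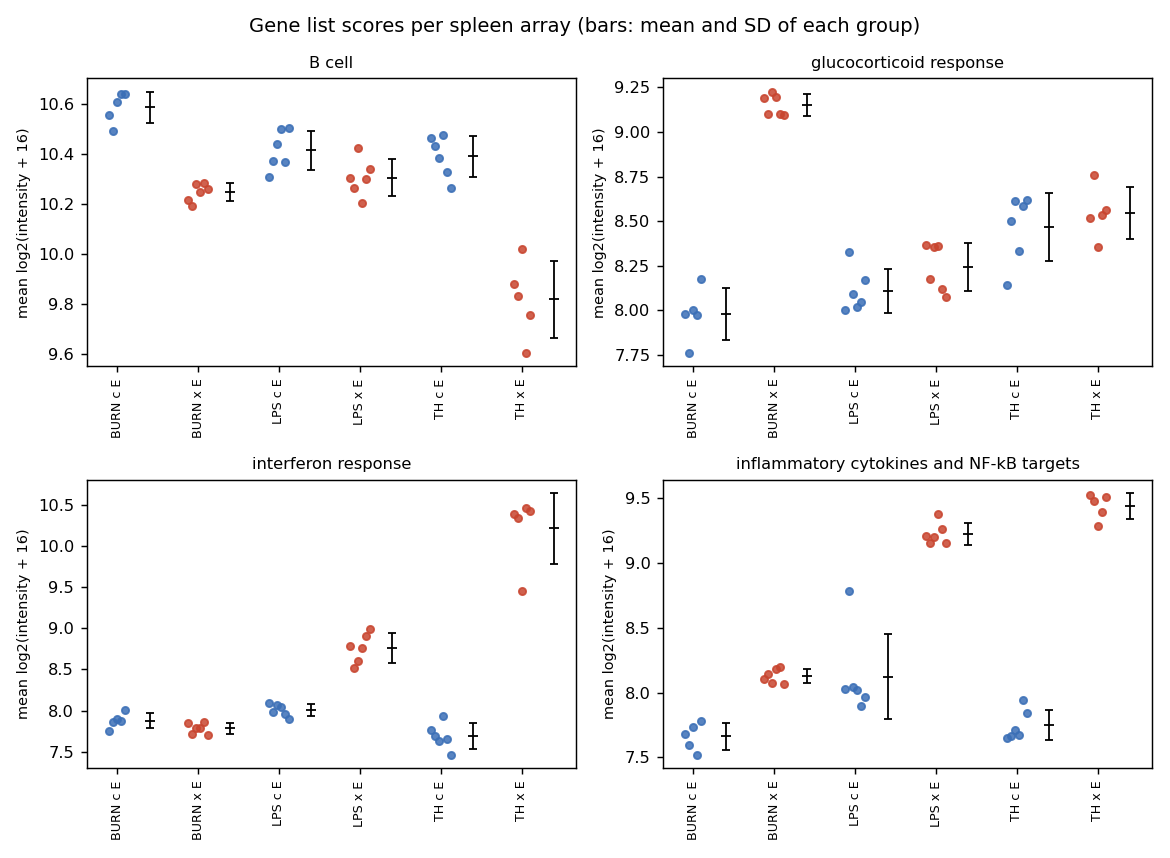
List score of each spleen array (y axis, mean log2 value of the list's members) by group, with the mean and SD of each group. The lists are B cell, glucocorticoid, interferon response and inflammatory genes. The median x minus c difference of interferon response genes was 2.69 in trauma-hemorrhage and 0.73 in LPS spleen. That of the glucocorticoid list was 1.24 in burn spleen.

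In LPS spleen (6 x and 6 c arrays) fewer genes passed, and most were higher, led by genes of inflammation. Cxcl2 rose by 3.58 ± 0.52 (11.9-fold), Acod1 by 3.56 ± 0.36, Clec4e by 3.06 ± 0.33 and Cd14 by 2.29 ± 0.16. The interferon-induced chemokines Cxcl10 and Cxcl9 rose by 2.91 ± 0.21 and 2.38 ± 0.14, and Ccrl2, a chemokine-binding receptor, by 2.76 ± 0.22. Slc40a1 fell most, at -1.85 ± 0.14, followed by the potassium channel Kcnj10 (-1.69 ± 0.16), Hpgd, which degrades prostaglandins (-1.36 ± 0.17), and Rgs2 (-1.26 ± 0.14). Each lay on the named side in 6 of 6 x arrays. Another probe set of Slc40a1 differed by -0.95 and another of Hpgd by -0.41.

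The inflammatory list rose in 17 of 27 members and fell in 0 (21 adjusted over the list alone). The inflammatory median was 0.67, with adjusted p = 8.3e-35, and adjusted p = 0.0140 with an estimated correlation. Interferon response genes rose in 16 of 21 (18 adjusted over the list alone), with Ifit1 at 2.06 ± 0.19. The interferon median was 0.73, with adjusted p = 2.9e-35, and adjusted p = 0.00330 with an estimated correlation. Acute phase genes rose in 6 of 13 (8 adjusted over the list alone). The acute phase median was 0.83, with adjusted p = 1.2e-14, and adjusted p = 0.0200 with an estimated correlation. Neutrophil genes rose in 9 of 14 (11 adjusted over the list alone). The neutrophil median was 0.82, with adjusted p = 3.6e-15, and adjusted p = 0.0845 with an estimated correlation. Apoptosis genes rose in 5 of 13 (6 adjusted over the list alone). The apoptosis median was 0.16, with adjusted p = 5.9e-09, and adjusted p = 0.00595 with an estimated correlation. Heat shock genes rose in 3 of 16 (5 adjusted over the list alone), with a median of 0.06. Their test gave adjusted p = 5.5e-05, and adjusted p = 0.0415 with an estimated correlation.

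The remaining calls in LPS spleen did not hold with an estimated correlation. Red pulp macrophage genes had 1 member higher, Spic at 0.92 ± 0.16, and 1 lower of 11 (1 and 6 adjusted over the list alone). The macrophage median was -0.23, with adjusted p = 4.0e-04, and adjusted p = 0.282 with an estimated correlation. B cell genes fell in 2 of 14 (1 higher and 2 lower adjusted over the list alone). The B cell median was -0.10, with adjusted p = 0.0121, and adjusted p = 0.386 with an estimated correlation. T cell genes fell in 1 of 17, Cd28 at -0.57 ± 0.12 (1 higher and 5 lower adjusted over the list alone). The T cell median was -0.12, with adjusted p = 0.0196, and adjusted p = 0.386 with an estimated correlation. Immediate early genes had 3 higher and 1 lower of 22 (4 and 1 adjusted over the list alone), with a median of 0.11. Here the test gave adjusted p = 0.00330, and adjusted p = 0.282 with an estimated correlation. The glucocorticoid list had 1 higher of 12, Ddit4 at 0.62 ± 0.16 (5 higher and 1 lower adjusted over the list alone). The glucocorticoid median was 0.21, with adjusted p = 0.00902, and adjusted p = 0.350 with an estimated correlation. In all, 429 genes passed, 307 higher and 122 lower. With the title-number run as a block 443 passed, within the first run 370 and within the second 230.

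In trauma-hemorrhage spleen (5 x and 6 c arrays) interferon response genes were among the largest rises. Ifit1, an interferon-induced protein that binds foreign RNA, rose by 4.49 ± 0.18 (22.5-fold), Mx1, an antiviral GTPase, by 4.01 ± 0.21 and Ifit3 by 3.85 ± 0.20. Cxcl10 rose by 4.18 ± 0.16 and Slfn4 by 3.84 ± 0.35, beside Acod1 at 4.27 ± 0.20, Cxcl2 at 4.20 ± 0.27 and the chemokine Ccl4 at 3.96 ± 0.14. The largest falls included genes of lymphocytes. Fcer2a, the low-affinity receptor of B cells for IgE, changed by -2.50 ± 0.21, Thy1, a T cell surface protein, by -1.84 ± 0.08 and Slc40a1 by -2.35 ± 0.19. Hpgd changed by -2.22 ± 0.14 and Cd55 by -2.05 ± 0.14. Kcnj10 changed by -2.40 ± 0.19 and Emilin3 by -2.04 ± 0.36, each with 1 of 5 x arrays at the floor. Each gene lay on the named side in 5 of 5 x arrays. Another probe set of Slc40a1 differed by -1.52.

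All 23 measured interferon response genes rose, also adjusted over the list alone. The interferon median was 2.69, with adjusted p = 3.0e-29, and adjusted p = 0.0686 with an estimated correlation. The inflammatory list rose in 22 of 25, also adjusted over the list alone, with a median of 1.50 and a mean of 1.76. The test gave adjusted p = 5.1e-23, and adjusted p = 0.00145 with an estimated correlation. Apoptosis genes rose in 8 of 14 (8 higher and 1 lower adjusted over the list alone), with Casp4 at 2.29 ± 0.15. The apoptosis median was 0.53, with adjusted p = 6.1e-06, and adjusted p = 0.0277 with an estimated correlation. Acute phase genes rose in 6 of 10, also adjusted over the list alone. The acute phase median was 0.95, with adjusted p = 1.2e-04, and adjusted p = 0.191 with an estimated correlation. Neutrophil genes rose in 7 of 15 (7 higher and 1 lower adjusted over the list alone). The neutrophil median was 0.56, with adjusted p = 0.00502, and adjusted p = 0.468 with an estimated correlation. B cell genes fell in 10 of 14 (11 adjusted over the list alone). The B cell median was -0.38, with adjusted p = 2.1e-05, and adjusted p = 0.223 with an estimated correlation. T cell genes fell in 10 of 17 (1 higher and 10 lower adjusted over the list alone). The T cell median was -0.38, with adjusted p = 1.5e-04, and adjusted p = 0.282 with an estimated correlation. In all, 3039 genes passed, 1184 higher and 1855 lower.

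A set of 20 genes was higher in x in all 6 comparisons, against 0.0137 if the calls of each were independent, of 7195 genes tested in all. They were Acod1, Arg2, Birc3, Ccrl2, Cd14, Clec4e, Cxcl2, Dgat1, Dgat2, Ets2, Hdc, Pde12, Rnf19a, Samsn1, Slc15a3, Srgn, Stat3, Tiparp, Txnrd1 and Zfp281, chosen here after their values were seen. With the beta-actin ratio as a covariate not all of the set passed. In LPS and trauma-hemorrhage blood that ratio separates x from c arrays, so the losses do not decide whether the set holds. In LPS blood 0 of 18 called inflammatory genes passed with the covariate, among them Acod1, Birc3, Clec4e and Cxcl2. In trauma-hemorrhage blood 16 of 5553 called genes passed. Several of the set act in innate immunity. Cd14 rose by 2.12 ± 0.39 in burn, 1.17 ± 0.34 in LPS and 2.20 ± 0.21 in trauma-hemorrhage blood, and by 2.03 ± 0.15, 2.29 ± 0.16 and 3.40 ± 0.21 in the spleen of the same models. In burn blood of letter E alone, with the pair of c arrays that stood apart included, Cd14 did not pass (1.44, limma, adjusted p = 0.121). Ralgps2, also chosen after its values were seen, was lower in all 6, against 0.0157 if independent.

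LPS and trauma-hemorrhage spleen shared 246 genes higher in both, against 36.2 by chance (Fisher's exact test, p = 1.5e-181), and 107 lower in both, against 24.4, with 5 called in opposite directions. Their differences correlated at Pearson r = 0.674 and Spearman rho = 0.425 across 8906 genes, which are not independent replicates. The blood of the same models correlated at r = 0.00372 (rho = -0.115) across 9555 genes. There 331 genes were higher in both (283 by chance), 228 lower in both (447 by chance) and 994 called in opposite directions. These counts rest on the split of the trauma-hemorrhage blood calls into higher and lower, which turned with the scaling, as given above. Burn blood and burn spleen shared 291 genes higher in both (79.1 by chance) and 247 lower in both (106 by chance), at r = 0.400 across genes. In all, 15 pairs of comparisons were set side by side.

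**Figure D5:**
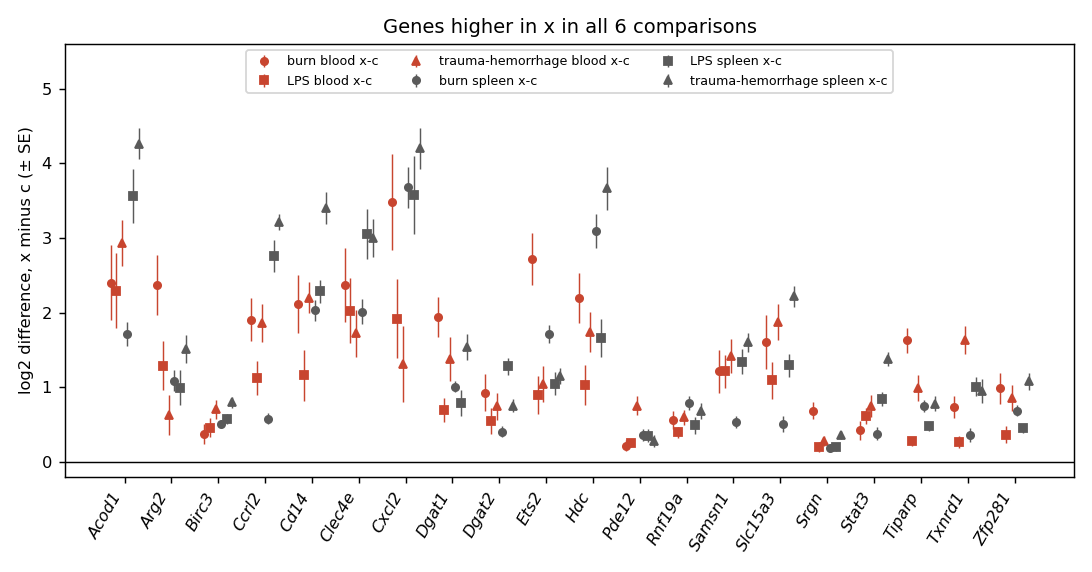
Log2 difference between x and c arrays of the 20 genes that were higher in all 6 comparisons, by tissue and model. Cxcl2 rose by 4.20 in trauma-hemorrhage spleen and by 1.32 in trauma-hemorrhage blood.

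The differences between models were tested directly, with the caution that each array set appears to have been processed separately. In blood, interferon response genes rose more with x in trauma-hemorrhage than in LPS arrays, with 19 of 22 higher, 0 lower and a median of 1.22. This difference had adjusted p = 1.5e-09, and adjusted p = 0.447 with an estimated correlation. They also rose more than in burn arrays, with 16 of 22 higher, 0 lower and a median of 1.34 (adjusted p = 8.9e-11, and adjusted p = 0.447 with an estimated correlation). B cell genes were lower with x in burn than in LPS blood, with 10 of 14 lower, 0 higher and a median of -0.60 (adjusted p = 2.1e-07, and adjusted p = 0.629 with an estimated correlation). Glucocorticoid genes were higher there, with 8 of 15 higher, 0 lower and a median of 0.73 (adjusted p = 2.4e-05, and adjusted p = 0.447 with an estimated correlation). Erythroid genes were lower with x in trauma-hemorrhage than in burn blood, with 9 of 13 lower, 0 higher and a median of -0.29 (adjusted p = 0.00252, and adjusted p = 0.629 with an estimated correlation). Monocyte genes were higher, with 7 of 10 higher, 0 lower and a median of 0.73 (adjusted p = 0.0192, and adjusted p = 0.629 with an estimated correlation). Within trauma-hemorrhage blood the erythroid and monocyte calls ended with the beta-actin covariate, as given above, and the differences between models were not tested with it.

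The numbers of genes whose x minus c differed in blood were 2194 between burn and LPS (989 higher and 1205 lower in burn), 5055 between trauma-hemorrhage and LPS (2149 and 2906) and 4631 between trauma-hemorrhage and burn (2059 and 2572). With the run as a block they were 2244, 5077 and 4602. Values as deposited turned the splits with trauma-hemorrhage, to 2644 higher and 1845 lower against LPS and to 2367 and 1850 against burn. Array medians subtracted did too, to 2591 and 2043 and to 2442 and 1829. For E minus A, Gsta2 was lower in trauma-hemorrhage than in LPS blood by -0.51 ± 0.10 (adjusted p = 0.0476, with 803 genes at an unadjusted p under 0.05). The call was lost with the run as a block and, among others, without LPS c of letter A replicate 3. Between burn and LPS limma called 0 genes for E minus A (343 at an unadjusted p under 0.05), and between trauma-hemorrhage and burn 0 (881).

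Between tissues, among E arrays, interferon response genes rose less with x in blood than in spleen of trauma-hemorrhage. Of 22, 16 were lower and 1 higher, with a median of -1.11 (adjusted p = 6.0e-12, and adjusted p = 0.136 with an estimated correlation). The inflammatory list did so too, with 11 of 25 lower, 1 higher and a median of -1.02 (adjusted p = 1.2e-04, and adjusted p = 0.522 with an estimated correlation). In burn, T cell genes were lower with x in blood than in spleen, with 9 of 17 lower, 0 higher and a median of -0.60 (adjusted p = 6.0e-12, and adjusted p = 0.0683 with an estimated correlation). Erythroid genes were higher, with 7 of 14 higher, 0 lower and a median of 0.47 (adjusted p = 7.1e-11, and adjusted p = 0.0374 with an estimated correlation). In LPS arrays 2 of 15 neutrophil genes rose more in blood and 0 less, and the list had a median difference of 0.93 (adjusted p = 7.9e-04, and adjusted p = 0.588 with an estimated correlation). In all, 465 genes differed between tissues in burn (213 higher and 252 lower in blood), 682 in LPS (274 and 408, and 678 with the run as a block) and 3361 in trauma-hemorrhage (1773 and 1588). The last split was 2409 and 1213 with values as deposited and 2359 and 1324 with array medians subtracted, and the burn count was 255 without spleen c replicate 1. Chance was not excluded for the burn and LPS counts. Of 100 splits of the same arrays, the real one included, 7 and 6 called at least as many genes.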

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

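The tests in this part were chosen after the results were seen, apart from the test of an E minus A change too small for the number of arrays. They include the choice of the 6 lists whose scores were checked for arrays that stand apart.

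Single arrays stood apart from their group by Dixon's test in 11 of 108 checks of list scores, where 5.4 would do so by chance. The neutrophil score was lowest, at 9.67, in LPS blood x of letter E replicate 5 and highest, at 9.39, in trauma-hemorrhage spleen c replicate 5. The erythroid score was lowest in trauma-hemorrhage blood c of letter E replicate 3 (9.88) and in burn spleen x replicate 2 (6.62), and highest in LPS spleen c replicate 1 (7.81). The interferon score was highest in LPS blood c of letter A replicate 5 (8.46) and lowest in trauma-hemorrhage spleen x replicate 3 (9.46). The inflammatory score was highest in LPS blood c of letter E replicate 5 (8.59) and in LPS spleen c replicate 2 (8.79), and lowest in LPS blood x of letter E replicate 5 (8.79) and in trauma-hemorrhage blood c of letter A replicate 3 (8.07).

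Differences between models or tissues passed limma's test of the difference itself in 7 comparisons, and 100 splits of the same arrays, the real one included, were counted for each. For x minus c in blood, 2194 genes differed between burn and LPS, 5055 between trauma-hemorrhage and LPS and 4631 between trauma-hemorrhage and burn. After each model's groups were centred, the real splits gave 2195, 5056 and 4631 genes, only the real split reached that many in each (1 of 100), and the highest others gave 814, 1809 and 233, so chance was excluded. For E minus A, 1 gene differed between trauma-hemorrhage and LPS blood, 9 of 100 splits gave as many and the highest other gave 1476, so chance was not excluded. Between blood and spleen, 465 genes differed in burn (7 of 100 splits, highest other 3541) and 682 in LPS (6 of 100, highest other 2182), so chance was not excluded for either, and 3361 in trauma-hemorrhage. There the real split after centring gave 3364 and 2 of 100 reached it, which excluded chance at 5 in 100 only, since 1 other split called more genes (3644).

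The same count for the other comparisons excluded chance for every comparison of x and c within a set, since only the real split (1 of 100) reached its count. Chance, here and above, means a random split of these arrays, and 1 of 100 is the smallest share that can be found. A handling difference that follows the code is not excluded, and title numbers do follow it in burn and trauma-hemorrhage spleen. Within each run of burn blood, LPS blood and LPS spleen, title numbers are also ordered by code. The run as a block cannot remove an effect of that order. The real and highest other counts were 2005 and 1138 in burn blood, 2811 and 607 in LPS blood, 5553 and 1952 in trauma-hemorrhage blood, 1938 and 815 in burn spleen, 429 and 49 in LPS spleen, and 3039 and 1 in trauma-hemorrhage spleen. For E minus A, 3 of 100 splits called at least the 3 genes of trauma-hemorrhage blood (highest other 33), whereas the real count was 0 in burn (highest other 0) and LPS blood (highest other 1897). It was also 0 for the interactions, with highest others of 0 in burn, 486 in LPS and 0 in trauma-hemorrhage blood, and for E minus A between burn and LPS (highest other 446) and between trauma-hemorrhage and burn (highest other 357). All 100 splits reach a count of 0 by construction, so for these 7 comparisons the number of splits says nothing. Splits that call many times the real count, such as 1897 in LPS blood, point to a structure of the samples that the letters do not follow.

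A first pattern is that blood x minus c called 2005 to 5553 genes and blood E minus A at most 3, although the labels describe E as injured. Other fits called more for E minus A: 257 in trauma-hemorrhage blood with all 12 blood groups in 1 fit, 59 among its c arrays alone, and 196 in LPS blood with array weights. Among arrays of letter A alone, described as sham, 11 of 29, 5 of 26 and 17 of 29 inflammatory genes differed between x and c in burn, LPS and trauma-hemorrhage, beside 1577, 1258 and 4069 of all 10247 genes. Such numbers, at least 5 per model, were to be expected once x and c differed over both letters, so they do not decide whether the letters separate sham from injured arrays, and that explanation stays open. An E minus A change too small for the number of arrays stays open, since its 95% interval excluded 0.5 times the x minus c difference in 62.2% of the genes at 2-fold or more (44.1% in burn, 18.6% in LPS and 78.0% in trauma-hemorrhage). Title-number runs that hide a difference were argued against, since with the run as a block at most 3 genes passed. A biological explanation, an injury response that A and E arrays share, was not tested.

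A second pattern is the lower beta-actin ratio of x arrays in LPS and trauma-hemorrhage blood. A shared RNA quality difference as the main source of both sets of calls was argued against by r = 0.00372 across genes. A smaller shared part could be masked by changes that differ between the models, so it stays open. With the ratio as a covariate the LPS calls had 98.1% of their median size (86.4% to 106% with each array left out, 0.29 before and after). Of these 2811 genes 76.0% kept their direction and 412 passed, while the median SE rose from 0.069 to 0.218. The 39 called members of the neutrophil, inflammatory and interferon lists in LPS blood had 16.3% of their size (-46.5% to 34.5%). The trauma-hemorrhage calls had 46.3% (36.5% to 73.9%, from 0.30 to 0.14, with the median SE from 0.072 to 0.158), 82.7% of them kept their direction and 16 passed. Among these, called interferon genes had 33.6% of their size (from 1.64 to 0.55), neutrophil genes 31.3% and inflammatory genes 82.6%. For the calls of each model, RNA quality and the code cannot be told apart, because the beta-actin ratio nearly follows the code in both sets. The same ratio of Gapdh did not follow it: x minus c was 0.155 in LPS blood, opposite in sign (permutation test, adjusted p = 0.0597), and -0.0819 in trauma-hemorrhage blood (adjusted p = 0.639). A general difference in RNA integrity, in either direction, would be expected to move both ratios, but 1 further control gene does not exclude it. Degraded RNA gives a higher ratio of 3' to 5' signal, so the lower beta-actin ratio does not mark x arrays as the more degraded. A treatment that alters the cells and their RNA together stays open as a biological explanation and was not tested.

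The last pattern is that interferon response genes rose more with x in trauma-hemorrhage than in LPS arrays, in blood by 1.22 and in spleen by 1.99 at the median. Over 4 scalings and both tissues the smallest median difference was 1.21, so the choice among these scalings did not make it. A scale factor of a whole set nearly cancels in x minus c, so this outcome was largely fixed in advance. Whether intensities were compressed to different degrees in the separate array sets was not tested. In blood RNA quality stays open, since the called interferon genes of trauma-hemorrhage had 33.6% of their size with the beta-actin ratio as a covariate. An exchange of single arrays would shrink the difference and was not weighed. An exchange of whole sets and a biological difference between the models stay open and were not tested.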

How the results depend on the processing

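Alternatives chosen after seeing the data were scaling within each array set, single title-number runs, leaving out the pair of burn c arrays and the beta-actin covariate, and the others were planned. Among named genes, 245 outcomes lost the call, 33 gained one, 3 called ones changed sign and 4994 did none of these. Among lists the numbers were 171, 72, 22 and 3039. Sign changes were counted for results called in the main fit only, so the 4994 and 3039 can hold uncalled results that changed direction. Counts of x minus c within a set moved by at most 1.5 times under other pseudocounts, scalings, filters and every probe set on its own. Signal over background limits what can be seen: up to 7.43% of the probe sets of an array were at the floor, where a fall cannot be measured. The estimated correlation ended 7, 7 and 5 list calls of E minus A in burn, LPS and trauma-hemorrhage, 14, 7 and 11 of x minus c in blood and 10, 6 and 5 in spleen. No paired analysis was possible because the labels give no number that pairs single arrays of different groups, only runs of title numbers, which were used as blocks. Where no construction is named below, the cause was not tested.

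Counts of E minus A, of interactions and of E minus A between models, all near 0, moved with most choices. With a pseudocount of 64, 1 gene passed E minus A in LPS blood, 15 in trauma-hemorrhage blood and 1 between trauma-hemorrhage and burn, and with a pseudocount of 1 it was 0 between trauma-hemorrhage and LPS. With values as deposited the counts were 0 for E minus A in trauma-hemorrhage blood, 23 for the burn interaction and 0 for E minus A between trauma-hemorrhage and LPS. With array medians subtracted they were 5 in trauma-hemorrhage blood, 0 between trauma-hemorrhage and LPS, and 451 between LPS blood and spleen for x minus c. No filter gave 1 in LPS blood, 1 for the LPS interaction, 0 between trauma-hemorrhage and LPS and 1 between trauma-hemorrhage and burn. A filter at the 50th percentile, which tests fewer genes, gave 13 in trauma-hemorrhage blood, 2 and 1 for those differences. Every probe set on its own, which tests more, gave 2 for the burn interaction, 3305 for x minus c between burn and LPS, and 0 and 1 for E minus A between trauma-hemorrhage and LPS and between trauma-hemorrhage and burn. The run as a block and scaling within each array set gave 0 between trauma-hemorrhage and LPS.

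Array weights gave 196 for E minus A in LPS blood, 3254 for x minus c in burn blood, 336 for the LPS interaction, 104, 62 and 1 for E minus A between burn and LPS, trauma-hemorrhage and LPS, and trauma-hemorrhage and burn, 3418 for x minus c between burn and LPS, and 1159 and 1959 between blood and spleen in burn and LPS. All 12 blood groups in 1 fit gave 257 for E minus A in trauma-hemorrhage blood and 1 for the burn interaction. With fewer arrays, c arrays alone gave 1 for E minus A in burn and 59 in trauma-hemorrhage blood, and x arrays alone 7 in LPS and 0 in trauma-hemorrhage blood. Letter A alone gave 1258 for x minus c in LPS blood, and letter E alone 661, 1650 and 3150 in burn, LPS and trauma-hemorrhage blood. The first run alone gave 0 for E minus A in trauma-hemorrhage and 1240 and 1257 for x minus c in burn and trauma-hemorrhage blood, and the second 0, with 58 in burn blood, 470 in LPS blood and 230 in LPS spleen. A 2-fold threshold, stricter by construction, gave 0 for E minus A in trauma-hemorrhage blood and between trauma-hemorrhage and LPS, and for x minus c 102, 43 and 236 in blood and 105, 68 and 291 in spleen of burn, LPS and trauma-hemorrhage, 122, 422 and 391 between burn and LPS, trauma-hemorrhage and LPS, and trauma-hemorrhage and burn, and 55, 45 and 279 between blood and spleen. The beta-actin covariate gave 1153 in LPS and 16 in trauma-hemorrhage blood, and leaving out the burn pair gave 9 for the burn interaction.

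List medians changed sign for E minus A among burn x arrays alone (neutrophil -0.081, B cell 0.17, inflammatory -0.060, MHC class II 0.067, acute phase -0.13, ribosomal proteins 0.11, oxidative phosphorylation 0.012), without the burn pair (neutrophil -0.018, inflammatory -0.0081, ribosomal proteins 0.021), among LPS c arrays alone (neutrophil -0.23, inflammatory -0.084, acute phase -0.088, ribosomal proteins 0.034) and in the first LPS run (ribosomal proteins 0.0068). For x minus c they did so for ribosomal proteins in burn letter E alone (0.019) and in the second LPS run (0.019). With the beta-actin covariate the test or value changed sign in LPS blood for Lcn2 (-0.057), Usp18 (-0.25) and Casp4 (-0.22) and the lists neutrophil (median 0.098), interferon (-0.081) and acute phase (-0.033), and in trauma-hemorrhage blood for neutrophil (-0.10) and erythroid (-0.013).

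Leaving out each array in turn gave counts, lowest to highest, of 0 to 0, 0 to 7 and 0 to 81 for E minus A in burn, LPS and trauma-hemorrhage blood, 1722 to 2494, 2478 to 3061 and 5201 to 5723 for x minus c, 0 to 2, 0 to 71 and 0 to 0 for the interactions, and 1471 to 2317, 334 to 522 and 2640 to 3092 in spleen. Between models they were 0 to 0, 0 to 8 and 0 to 7 for E minus A (burn and LPS, trauma-hemorrhage and LPS, trauma-hemorrhage and burn) and 2027 to 2376, 4748 to 5231 and 4358 to 4848 for x minus c, and between tissues 255 to 602, 504 to 883 and 2892 to 3680.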

Other observations

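Leaving out the burn pair, single title-number runs and the beta-actin covariate were chosen after the results were seen, the other tests in this part were not, and no explanation is offered. Genes of antigen presentation and energy metabolism, not described above, also differed between x and c arrays in blood. In burn blood MHC class II genes fell in 5 of 9 (8 adjusted over the list alone, median -0.34, adjusted p = 8.0e-04, and adjusted p = 0.462 with an estimated correlation), with H2-DMa, which loads peptides, at -0.91 ± 0.12. In letter E alone neither the list (median -0.14, adjusted p = 0.0519) nor H2-DMa (-0.55, adjusted p = 0.0547) passed, nor did oxidative phosphorylation genes, given below (-0.06, adjusted p = 0.0543). These letter E fits included the pair of burn c arrays that stood apart. Hypoxia and glycolysis genes rose in trauma-hemorrhage blood, with 9 higher and 2 lower of 15 (9 and 2 adjusted over the list alone, median 0.54, adjusted p = 0.00335, and adjusted p = 0.462 with an estimated correlation), led by Hif1a, the oxygen-regulated transcription factor, at 1.23 ± 0.12 (0.05 in another of its 4 probe sets) and Ldha, which makes lactate, at 0.93 ± 0.11. With the beta-actin covariate that list call ended (median 0.018, adjusted p = 0.531). Ribosomal protein genes were higher in trauma-hemorrhage blood (22 higher and 1 lower of 42, 23 and 1 adjusted over the list alone, median 0.33, adjusted p = 3.7e-06, and adjusted p = 0.523 with an estimated correlation). They were lower in burn blood over both letters, with a median of 0.019 in letter E alone (1 higher and 13 lower of 42, 1 and 24 adjusted over the list alone, median -0.16, adjusted p = 2.4e-05, and adjusted p = 0.523 with an estimated correlation). In LPS blood they were lower too, except in the second title-number run at 0.019 (5 higher and 16 lower of 42, 6 and 16 adjusted over the list alone, median -0.07, adjusted p = 0.0449, and adjusted p = 0.754 with an estimated correlation). Their difference between trauma-hemorrhage and burn was tested and passed (30 of 40 higher and 0 lower, median 0.48, adjusted p = 7.4e-10, and adjusted p = 0.629 with an estimated correlation).

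Oxidative phosphorylation genes were lower in burn blood (1 higher and 22 lower of 78, 2 and 26 adjusted over the list alone, median -0.13, adjusted p = 1.6e-04, and adjusted p = 0.523 with an estimated correlation). They were split in trauma-hemorrhage blood, and the call ended with the beta-actin covariate at adjusted p = 0.185 (29 higher and 18 lower of 77, 29 and 20 adjusted over the list alone, median 0.07, adjusted p = 0.0199, and adjusted p = 0.603 with an estimated correlation). In burn spleen cell cycle genes fell in 7 of 16 (1 higher and 7 lower adjusted over the list alone, median -0.18, adjusted p = 0.00408, and adjusted p = 0.351 with an estimated correlation), with the proliferation marker Mki67 at -0.81 ± 0.10 and Rrm2, a subunit of ribonucleotide reductase, at -0.86 ± 0.11. Endothelial and stromal genes fell there in 4 of 8 (5 adjusted over the list alone, median -0.29, adjusted p = 0.0194, and adjusted p = 0.386 with an estimated correlation), with the matrix protein Sparc at -0.39 ± 0.08. Ribosomal protein genes had there 7 higher and 1 lower of 45 (9 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.0330, and adjusted p = 0.157 with an estimated correlation). For E minus A the MHC class II median was -0.10 in burn blood, and 0.067 among x arrays alone (0 of 9 passed, also adjusted over the list alone, adjusted p = 0.0140, and adjusted p = 0.682 with an estimated correlation). The oxidative phosphorylation median was -0.04 in burn blood, and 0.012 among x arrays alone (0 of 78 passed, also adjusted over the list alone, adjusted p = 0.00540, and adjusted p = 0.803 with an estimated correlation). The ribosomal protein median was -0.05 in burn blood, but 0.11 among x arrays alone and 0.021 without the pair of burn c arrays (0 of 42 passed, also adjusted over the list alone, adjusted p = 0.00746, and adjusted p = 0.808 with an estimated correlation). In LPS blood it was -0.04, but 0.034 among c arrays alone and 0.0068 in the first title-number run (0 of 42 passed, also adjusted over the list alone, adjusted p = 0.00540, and adjusted p = 0.803 with an estimated correlation).

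Dendritic cell genes did not pass in any comparison of letters or codes, and the 3 measured genes of eosinophils, basophils and mast cells, tested in spleen of burn and LPS only, did not pass there (adjusted p = 0.251 and 0.284). Median, mean and test of a list differed in sign in several comparisons, and none of these lists passed. They were T cells for E minus A in burn blood, NK cells, dendritic cells, red pulp macrophages, hypoxia and cell cycle for E minus A in LPS blood, and for x minus c platelets and red pulp macrophages in burn blood, red pulp macrophages and cell cycle in trauma-hemorrhage blood, and in LPS blood monocytes, T cells, NK cells, red pulp macrophages, immediate early, glucocorticoid, MHC class II, hypoxia and cell cycle genes. In spleen they were platelets, apoptosis and acute phase genes in burn, platelets, dendritic cells and eosinophils in LPS, and glucocorticoid, heat shock and cell cycle genes in trauma-hemorrhage. Before normalization, the 90th percentile of intensity was higher in x than in c arrays of trauma-hemorrhage blood by 62.5 (permutation test, adjusted p = 2.4e-04, 11 arrays each), the last of the 24 quality comparisons that passed.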
